A study of Mus musculus with 4 samples.

How the data were processed

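Single-cell RNA profiles were analysed from 4 mouse retina samples, 2 control and 2 Jarid2_cKO, each made from the 2 pooled retinas of 1 embryo at embryonic day 18.5. Per the labels, control animals carried floxed Jarid2 on both alleles and Jarid2_cKO animals also carried 1 copy of Rax-CreERT2, a tamoxifen-dependent Cre recombinase at the Rax locus. All animals received tamoxifen. No control carried the Cre, so an effect of Cre cannot be parted from loss of Jarid2 in any comparison. A control and a Jarid2_cKO littermate were dissected on each of 2 days, and the replicate numbers I and II mark the day. Batch I was prepared with the version 3 and batch II with the version 3.1 kit for 3' single-cell expression. Batch I was sequenced deeper, per the labels. The replicate number therefore pairs a control with a Jarid2_cKO sample of the same litter, day and kit. In progenitors the log2 CPM difference between the replicates I and II of the control correlated across 15592 genes with that of Jarid2_cKO (r = 0.815, where genes are not independent replicates). That correlation was between 0.511 (retinal ganglion cells) and 0.775 (all cells) in the other sets of cells.

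Each sample came as deposited UMI counts per gene and barcode, whole numbers that the authors made with Cell Ranger against mm10, per the submitters' processing notes. Those notes name Cell Ranger 3.1.0 while the file headers name 6.0.1, and the gene model release is not given in the sources used here. The strand setting of the counting is also not given, so opposite-strand overlaps are marked for Jarid2, Foxp1, Rax and the genes named as past the threshold over all genes. The files held 32285 genes, of which 32158 gene identifiers matched GENCODE release M21 of the same build. Coordinates are taken from that release and 1-based. Cell classes were those of the deposited annotation, made with Seurat 4.0.3 per the submitters' processing notes, which names 9 classes, cluster numbers of integrated data and DoubletFinder calls. It covered 31759 of 39814 barcodes, and the 2087 cells called doublets there were left out, leaving 29672 singlets. Annotated singlets had under 7.5% mitochondrial UMIs, as read from the counts. The deposited tables of scaled values carry no gene names and were not used.

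Depth over the singlets was 130586576 UMIs in control replicate I, 116651432 in Jarid2_cKO replicate I, 41752750 in control replicate II and 57380777 in Jarid2_cKO replicate II. Median UMIs per singlet were 9957, 11678.5, 8243 and 9071.5. Intervals of single-library shares are exact 95% binomial intervals and cover counting error only.

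The animal was the unit of every test of the genotype effect on single genes and class shares. The list tests given below, at their preset correlation, compare genes with genes, so their p-values do not measure spread between animals. In the closing section 1 test also counts genes. Counts were summed per sample and class for the 7 classes with at least 30 cells in each sample (horizontal cells and glia fell short), and over all singlets. Each set was filtered with filterByExpr, scaled with TMM and tested in edgeR 4.0.16 with the quasi-likelihood test, genotype as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. The first alternative adds the replicate number as a block. CPM values use TMM-scaled library sizes, and log2 CPM values of single libraries use a prior count of 2. Class shares were tested with the same edgeR test on cell numbers. Differences of the genotype effect between progenitors and other classes were formed within each animal on the log2 CPM scale and tested with limma 3.58.1. All tests are two-sided unless stated. A single value from 2 against 2 animals cannot reach an exact permutation p under 0.333, so no single-value test was run.

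Lists fixed before the data were examined, 25 in all, were tested with limma camera at a preset inter-gene correlation of 0.01 where at least 3 genes were tested, with an estimated correlation and fry as alternatives. They hold early progenitor, late progenitor, pan progenitor, neurogenic, retinal ganglion cell, amacrine cell, horizontal cell, cone, rod, photoreceptor, bipolar cell, Mueller glia, S phase, G2M phase, Notch pathway, PRC2 component, Hox, non-retinal developmental, microglia, vascular, astrocyte, erythroid, pigment epithelium and ciliary margin, lens, and dissociation stress genes. With an estimated correlation the test rests on the few residual degrees of freedom of 4 samples, and no list passed in any set of cells. The simulations did not run it, so a call lost there leaves a list undecided. Some lists share members, so their calls are not independent. The neurogenic and Notch lists share Dll1, Dll3 and Dll4, and the Notch and late progenitor lists share Hes5. Mueller glia and late progenitor lists share Rlbp1, Glul, Apoe and Dkk3. Named genes follow a rule fixed at the same time as the lists. Jarid2, Foxp1 and Rax are given in every class. In progenitors the 10 genes of largest positive and 10 of largest negative log2 fold change are named among those past the threshold, with the same sign in both littermate pairs and an average of at least 10 CPM, and in other classes the 3 largest. Where the fit without block gave fewer, the list was filled from the fit with the block, which was so for all of them. Members of the fixed lists past the threshold are also named. Adjustment over a list alone, given for some lists, was not part of that rule. It corrects within a single list and class only, so it is weaker than the threshold over all genes. Unnamed loci were left out of the naming, 3 in progenitors, 3 in cones, 4 in rods and 1 in amacrine cells among the genes past the threshold with the block.

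Counts were simulated with the real mean of each pair, library sizes and batch difference, a common dispersion for all genes of a class, and 200 changed genes. That dispersion came from the fit with the block, so this fit met its own estimate of spread in the simulated counts. On these the fit without block recovered 0 of 64 genes changed 4-fold in progenitors (15621 genes run), and the fit with the block recovered 64. Of genes changed 1.5-fold it recovered 60.6% in progenitors, 20.0% in cones (9557 genes) and 14.5% in rods (7898 genes). False calls were 4.89% of calls in progenitors, 5.04% in cones and 1.03% in rods. Genes were drawn independently, with the same change in both pairs. These shares therefore do not cover dispersion that differs between genes, or pairs that disagree. Nor do they check whether the spread in the fit with the block is right. A simulated 2-fold cone share was found as 1.97-fold.

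The other alternatives were DESeq2's size factors within edgeR, no low-count filter, DESeq2 1.42.0 (R 4.3.3), UMI counts thinned to the mean UMI per cell of the shallowest sample, equal numbers of cells, own Leiden clusters (scanpy 1.11.5, 35 clusters named by fixed markers) for class shares, and each sample left out. Scrublet's automatic threshold marked 0, 0, 9 and 4 cells in control replicate I, Jarid2_cKO replicate I, control replicate II and Jarid2_cKO replicate II, too few to have worked. As an alternative chosen after seeing the data, the top-scoring cells were left out instead, as many per sample as the authors called doublets. The fixed markers named 3 own clusters cone although most of their cells are photoreceptor precursors or progenitors in the authors' annotation, so under that naming no share is given for cones, rods and precursors. The reference for the naming had been changed from the overall mean to the median cluster after a first naming had been seen. As a later alternative, chosen after both, each own cluster took the authors' class that most of its cells hold, which rests on the authors' names and leaves no cluster to rods. Tests of explanations are given in the closing section.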

Results

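The study profiled single cells of embryonic day 18.5 mouse retinas in which Jarid2, an accessory subunit of the Polycomb repressive complex 2, was deleted with a tamoxifen-induced Cre expressed from the Rax locus. It asked how loss of Jarid2 alters the temporal progression of retinal progenitors, with the transcription factor Foxp1 as the proposed target. There were 2 control and 2 Jarid2_cKO animals, in 2 littermate pairs that also differ in kit and dissection day. Singlets numbered 10959 in control replicate I, 8642 in Jarid2_cKO replicate I, 4479 in control replicate II and 5592 in Jarid2_cKO replicate II. Median UMIs per singlet lay between 8243 and 11678.5.

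Cones, the photoreceptors of daylight vision, made up a larger share of the Jarid2_cKO retinas in both littermate pairs. They were 1.95% of singlets in control replicate I (214 cells, 95% interval 1.70 to 2.23%) and 3.54% in Jarid2_cKO replicate I (306 cells, 3.16 to 3.95%). In pair II the shares were 3.06% (137 cells, 2.57 to 3.61%) and 5.42% (303 cells, 4.84 to 6.04%). The mean share was 2.51% ± 0.782 in control and 4.48% ± 1.33 in Jarid2_cKO (SD, n = 2). With the replicate block the share of cones rose 1.79-fold (95% interval 1.45 to 2.22, edgeR adjusted p = 0.00134), whereas without the block the log2 ratio of 0.85 did not pass (adjusted p = 0.393). That unblocked ratio was 0.55 without control replicate I and 0.51 without Jarid2_cKO replicate II, in fits that mix genotype with batch. In own clusters, each given the authors' class that most of its cells hold, the log2 ratio of cones was 0.83 with the block (edgeR adjusted p = 0.0111) and 0.84 without it (0.0535), a grouping chosen after 2 earlier namings of the clusters had been seen. Progenitors were the largest class at 58.6 and 52.1% of control singlets and 54.1 and 46.7% of Jarid2_cKO singlets. Their log2 ratio of −0.14 (95% interval −0.34 to 0.07 with the block) did not pass. Retinal ganglion cells were 4.22 and 2.90% in control and 2.93 and 2.83% in Jarid2_cKO, with a blocked log2 ratio of −0.34 that did not pass after adjustment over the 9 classes (edgeR adjusted p = 0.140). Amacrine cells, neurogenic cells, photoreceptor precursors, rods, horizontal cells and glia also did not pass, with blocked log2 ratios from −0.16 for rods to 0.69 for horizontal cells. Horizontal cells and glia rested on 8 to 33 cells per sample.

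**Figure D1:**
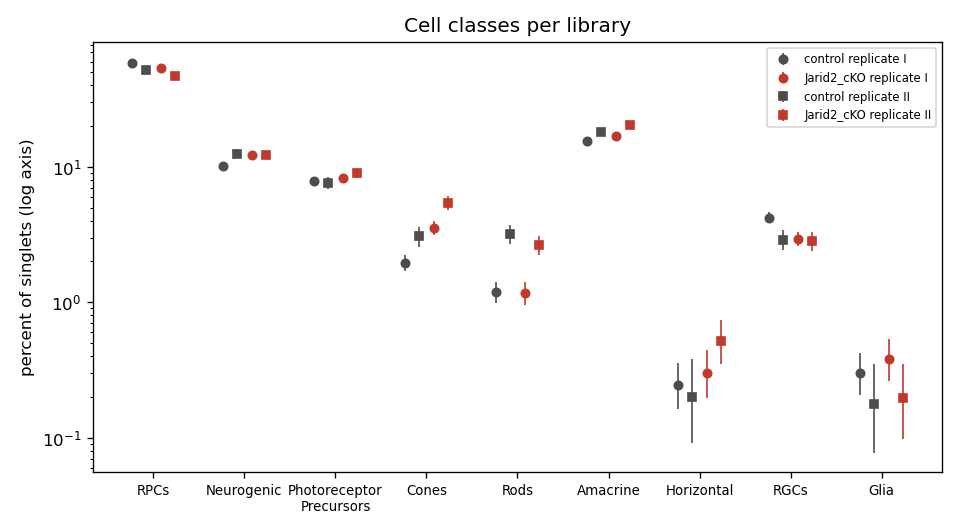
Share of each cell class among singlets (percent, log axis) in the 4 libraries, with control in grey and Jarid2_cKO in red, circles for replicate I and squares for replicate II; bars are exact 95% binomial intervals. Cones were 1.95 and 3.06% in the control and 3.54 and 5.42% in the Jarid2_cKO libraries.

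The targeted gene, Jarid2 (ENSMUSG00000038518, chromosome 13, 44729474 to 44921643, plus strand, mm10), had similar levels in both genotypes. In progenitors it was at 28.2 and 30.4 CPM in control replicates I and II and at 24.8 and 30.6 CPM in Jarid2_cKO. Its blocked log2 fold change there was −0.09 (95% interval −0.28 to 0.10), and it lay between −0.21 in rods and 0.05 in amacrine cells in the other classes, with a smallest adjusted p of 0.921. The 3' tags may lie outside the deleted exons, which the labels do not give, so the level does not check the genotype labels.

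Foxp1 (ENSMUSG00000030067, chromosome 6, 98925338 to 99522721, minus strand, overlapped by Gm20705 on the same strand), a forkhead transcription factor, was higher in Jarid2_cKO progenitors of both pairs. It averaged 77.7 ± 6.99 CPM in control and 119.5 ± 5.82 CPM in Jarid2_cKO (SD, n = 2). With the replicate block Foxp1 rose 1.54-fold in progenitors (log2 0.62, SE 0.08, edgeR adjusted p = 0.0102) and 1.76-fold in neurogenic cells (log2 0.82, SE 0.10, adjusted p = 0.0160). Without the block neither passed, at log2 0.62 and 0.82. The blocked log2 fold change of Foxp1 was 0.45 in photoreceptor precursors (adjusted p = 0.305), 0.45 in amacrine cells (0.242), 0.31 in rods (0.926), 0.28 in retinal ganglion cells and 0.21 in cones (0.941), none of which passed. Rax (chromosome 18, 65928277 to 65939787, minus strand), a homeobox gene of the eye field that carries the Cre driver, did not pass in any class. In progenitors Rax levels differed more between the pairs than between genotypes, at 311 and 342 CPM in pair I and 594 and 576 CPM in pair II. Its blocked log2 fold change was 0.05 there. It was −0.45 in neurogenic cells (edgeR adjusted p = 0.168, the smallest of any class), −0.48 in rods and −0.28 in cones. In photoreceptor precursors and amacrine cells it was −0.20. Rax was lower in both pairs in these 5 classes, and higher in both in retinal ganglion cells (0.28).

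In progenitors 42 genes passed with the replicate block, 26 higher and 16 lower in Jarid2_cKO, and 0 of 15592 passed without it. Beside that 0, edgeR gave 91 genes at an unadjusted p under 0.05, and DESeq2 called 9 genes without and 30 with the block. The 10 named genes of largest rise, all higher in both pairs, were Lman1, Lrrn3, Reln, Pcdh7, Sox2ot, Sfrp2, Robo1, Itm2a, Shisa2 and Tubb6. Lman1, a cargo receptor between endoplasmic reticulum and Golgi (ENSMUSG00000041891, chromosome 18, 65980738 to 66022580), went from 448 ± 89.8 to 1271 ± 184 CPM (SD, n = 2), a log2 change of 1.51 (SE 0.09, edgeR adjusted p = 6.65e-05). Lman1 lies 41.0 kb and Tubb6 1451 kb from Rax, the locus of the Cre driver that only Jarid2_cKO animals carry. Lrrn3, a leucine-rich repeat membrane protein, rose by 1.34 on the log2 scale (adjusted p = 4.83e-04) and the secreted glycoprotein Reln by 1.20 (adjusted p = 0.00157). The protocadherin Pcdh7 rose 2.06-fold, from 15.4 to 32.0 CPM. Sox2ot, a non-coding transcript that overlaps Sox2 on the same strand, rose 1.84-fold, and counts of the overlapping pair cannot be fully parted. Sfrp2, a secreted Wnt modulator, rose 1.81-fold, from 93.2 ± 1.28 to 168 ± 6.90 CPM. The Slit receptor Robo1, Itm2a, Shisa2 and the beta tubulin Tubb6 rose 1.62-fold to 1.74-fold.

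Only 7 lower genes met the naming rule in progenitors. The serine protease Prss56 fell most, from 8.58 to 1.69 CPM in pair I and from 26.8 to 3.88 CPM in pair II, a log2 change of −2.57 (SE 0.14, edgeR adjusted p = 5.92e-05). Cpne5, a copine, fell 1.82-fold, and the actin regulator Phactr1 and the fatty acid binding protein Fabp7 each fell 1.60-fold. Fabp7 was at 23.6 CPM in control progenitors against 1139 CPM in control rods. What part of its progenitor counts is free RNA from other cells was not tested. Gas1, a hedgehog co-receptor, had a log2 change of −0.54, as had the carbonic anhydrase Car2, which went from 173 ± 11.1 to 119 ± 13.3 CPM. Cox4i2, a subunit isoform of cytochrome c oxidase, fell 1.40-fold (adjusted p = 0.0489). With edgeR none of these calls was made without the block, and DESeq2 with the block did not call Fabp7 (adjusted p = 0.0535).

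**Figure D2:**
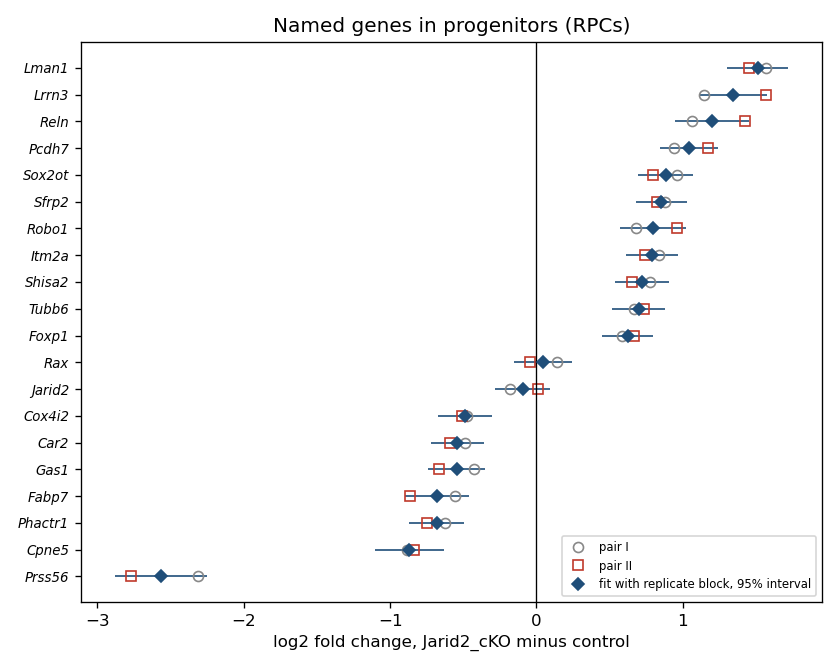
Log2 fold change (Jarid2_cKO minus control) of the named genes in progenitors; diamonds are the edgeR fit with the replicate block with 95% intervals, open circles pair I and open squares pair II. Lman1 (1.51) and Prss56 (−2.57) lie at the ends, and the points of both pairs share a sign for each gene except Jarid2 and Rax.

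Among the lists, early progenitor genes rose and late progenitor genes fell in Jarid2_cKO progenitors by camera at its preset correlation. Neither call held with an estimated correlation (adjusted p = 0.687 for the early and 0.777 for the late list), under which no list passed in any set of cells. The early list had a median log2 fold change of 0.17 over 14 genes (limma camera adjusted p = 1.46e-06), and 9 of them were higher in both pairs. With the block, 2 of the 14 rose, Sfrp2 and Foxp1, and 0 fell over all genes tested. Adjusted over the list alone, 4 rose, the others being Lin28b and Hmga2. Foxp1 is also the gene the study names. The late list had a median of −0.10 over 18 genes (adjusted p = 0.00793), and 11 were lower in both pairs. Of these Car2 fell over all genes tested, and adjusted over the list alone 4 fell, with Nfix, Crym and Apoe. Neurogenic genes (median −0.16 over 15, adjusted p = 0.00793), cone genes (−0.20 over 7, 0.00793) and G2M phase genes (−0.04 over 52, 0.0387) fell, and pigment epithelium and ciliary margin genes rose (0.27 over 6, 0.00582). These 4 lists also had an adjusted p of 0.777 with an estimated correlation, and none of the 6 passed with fry (smallest adjusted p over the 21 lists = 0.326). Of the ciliary margin genes Otx1 rose with the block when adjusted over the list alone. Counts of the cone transcripts Gnb3 and Opn1sw were lower by the same measure, but Opn1sw was at 3.21 CPM in control progenitors against 629 CPM in control cones, and the part of such counts that is free RNA was not tested outside cones.

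Beyond those 6 lists, 15 did not pass in progenitors, with camera adjusted p from 0.0892 to 0.946. These were the pan progenitor, retinal ganglion cell, amacrine, horizontal, rod, photoreceptor, bipolar, Mueller glia, S phase, Notch pathway, PRC2 component, non-retinal developmental, vascular, astrocyte and dissociation stress genes. The block added retinal ganglion cell genes (median 0.19, adjusted p = 0.0286; 0.677 with an estimated correlation). Of single members, the amacrine gene Meis2, a homeodomain factor, rose 1.43-fold with the block (adjusted p = 0.0295), and Fabp7 of the pan progenitor list fell as given above. PRC2 component genes had a median of −0.02 over 11 genes although the test pointed up, as it did for horizontal cell genes (median 0.00, mean 0.00) and dissociation stress genes (median −0.01, mean −0.03). Hox and erythroid genes had 0 tested members, and microglia and lens genes had 1 each.

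Neurogenic cells showed 12 genes past the threshold with the block, 8 higher and 4 lower. None of 12961 genes passed without it, where edgeR gave 86 at an unadjusted p under 0.05 and DESeq2 called 2 without and 7 with the block. With the block the count was 62 (23 higher, 39 lower) with top-scoring Scrublet cells left out, 34 (12 and 22) with equal numbers of cells and 113 (51 and 62) with no low-count filter, so most calls were lower rather than higher there. No low-count filter without the block gave 18. The LIM-only factor Lmo1 rose 4.01-fold (4.93 ± 0.986 to 20.3 ± 5.89 CPM, SD, n = 2, edgeR adjusted p = 0.00311), Meis2 2.22-fold and Sox2ot 2.13-fold. Car2 fell 1.78-fold, the mitochondrial protein gene Ndufa4l2 1.69-fold, Cox4i2 1.64-fold and Gadd45a, a growth arrest gene of the neurogenic list, 1.64-fold (adjusted p = 0.0335). DESeq2 with the block did not call Car2, Cox4i2 or Sox2ot (adjusted p from 0.111 to 0.265). Late progenitor genes fell as a list (median −0.26 over 18, camera adjusted p = 0.00701, and 0.542 with an estimated correlation), with 14 lower in both pairs. Adjusted over the list alone with the block, 7 fell and 1 rose, led by Car2, Hes5 and Apoe. Neurogenic genes (median −0.12, adjusted p = 0.0102) and Notch pathway genes (−0.08, 0.0206) fell too, each with an adjusted p of 0.542 with an estimated correlation. They had Neurog2 and Olig2 among 4 lower neurogenic genes and Hes5 and Hey1 among 3 lower Notch genes (Rbpj rose) adjusted over the list alone. Dll1 was among the lower genes of both lists, and Hes5 is also on the late progenitor list. With the block, amacrine cell genes (higher) and Mueller glia genes (lower) also passed, but not with an estimated correlation (adjusted p = 0.650 for both).

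Photoreceptor precursors had 4 genes past the threshold with the block and 0 without it (50 at an unadjusted p under 0.05, and 0 by DESeq2, which called 8 with the block). The count with the block was 0 with DESeq2 size factors (adjusted p = 0.0603 for each of the 4 genes), 53 with thinned UMIs (27 higher, 26 lower), 85 with equal numbers of cells (38 and 47), 113 with top-scoring Scrublet cells left out (57 and 56) and 140 with no low-count filter (74 and 66). No low-count filter without the block gave 10. Raxos1 rose 5.29-fold (2.46 and 5.43 CPM in control, 15.1 and 21.9 CPM in Jarid2_cKO), Lman1 2.14-fold and the adaptor gene Samsn1 2.10-fold, and the apolipoprotein gene Apoe fell 1.86-fold (186 ± 6.30 to 99.8 ± 2.86 CPM, SD, n = 2). Raxos1 (chromosome 18, 65937538 to 65940447, plus strand) overlaps Rax, the locus of the Cre driver, on the opposite strand, and whether the counting parted the strands is not given in the sources used here. In this class early progenitor (median 0.17) and retinal ganglion cell genes (0.17) rose, and late progenitor (−0.14), neurogenic (−0.23), rod (−0.20), Mueller glia (−0.19) and vascular genes (−0.11) fell, with camera adjusted p from 1.89e-05 to 0.0214. Each had an adjusted p of 0.512 with an estimated correlation. Vascular genes lost the call with the block (adjusted p = 0.0680), while pan progenitor and dissociation stress genes gained one (lower) that did not hold with an estimated correlation (adjusted p = 0.618). Rod and vascular genes did not pass with top-scoring Scrublet cells left out (adjusted p = 0.0602 and 0.757).

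In cones 44 genes passed with the block, 14 higher and 30 lower, and 0 of 9522 passed without it (84 at an unadjusted p under 0.05; DESeq2 called 1 gene without the block and 1 with it, Apoe). Opn1sw, the short-wave cone opsin, was at 378 and 880 CPM in control replicates I and II and at 149 and 105 CPM in Jarid2_cKO, a log2 change of −2.16 (SE 0.17, edgeR adjusted p = 5.86e-16). The pairs differed by more than that error, at −1.34 and −3.04, and DESeq2 with the block made no call for Opn1sw (adjusted p = 1). The potassium channel subunit gene Kcne2 fell 5.54-fold and the calcium-binding protein gene Cabp4 5.16-fold. Recoverin (Rcvrn) fell 4.22-fold, from 32.0 ± 0.825 to 8.14 ± 4.47 CPM (SD, n = 2), and Aipl1, a chaperone of the photoreceptor phosphodiesterase, 1.54-fold. The arrestin gene Sag fell 1.89-fold and Apoe 2.27-fold. Higher were Gsg1 (5.47-fold), Raxos1 (5.02-fold) and Lypd1 (4.67-fold). Cone genes fell as a list (median −0.21 over 7, camera adjusted p = 9.43e-05, and 0.712 with an estimated correlation), with 4 lower in both pairs and Opn1sw, Pde6h and Gnb3 lower adjusted over the list alone. Photoreceptor genes fell as well (median −0.13 over 6, adjusted p = 0.00978, and 0.712 with an estimated correlation), with 3 lower in both pairs, Rcvrn and Aipl1 among them. With the block, neurogenic (lower), retinal ganglion cell and amacrine genes (higher) also passed, but none did with an estimated correlation (adjusted p = 0.636 for each). Gsg1, Lypd1, Cabp4, Opn1sw and Rcvrn overlap another gene on the opposite strand, as do Lrrn3, Reln, Pcdh7, Sox2ot, Sfrp2, Phactr1, Gas1, Lmo1, Ndufa4l2, Gadd45a, Samsn1 and Junb in the other classes. After top-scoring Scrublet cells were left out the call count with the block was 12 (4 higher, 8 lower), and Aipl1, Cabp4, Raxos1, Rcvrn and Sag no longer passed (adjusted p from 0.0649 to 0.164). No low-count filter without the block gave 11 genes. The class had 137 to 306 cells per sample.

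**Figure D3:**
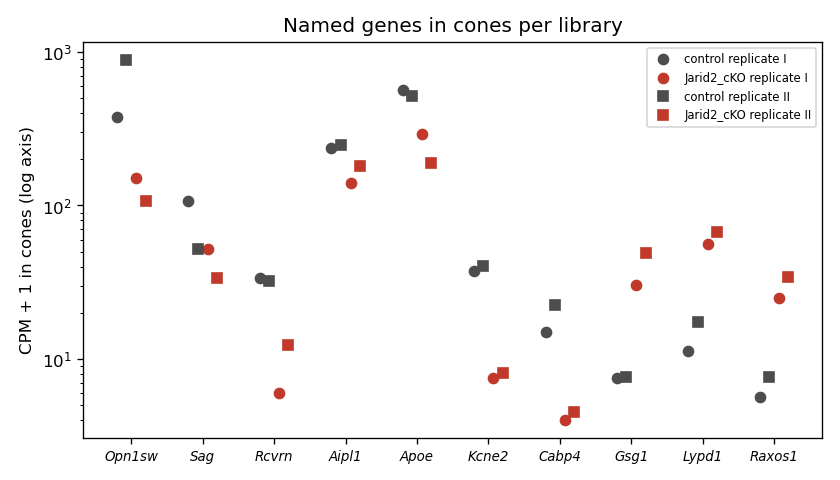
CPM plus 1 (log axis) of named genes in cones in each of the 4 libraries, control in grey and Jarid2_cKO in red, circles for replicate I and squares for replicate II. Opn1sw was at 378 and 880 CPM in control and 149 and 105 CPM in Jarid2_cKO cones.

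Rods, the photoreceptors of dim light, showed 52 genes past the threshold with the block, 22 higher and 30 lower, among 7930. Without the block 0 passed, with 87 at an unadjusted p under 0.05, and DESeq2 called 0 without and 1, Fabp7, with the block. Fabp7 fell 2.76-fold, from 1139 ± 437 to 421 ± 204 CPM (SD, n = 2, edgeR adjusted p = 2.06e-15), Opn1sw 2.29-fold, Apoe 2.27-fold, Sag 1.81-fold, Junb 1.95-fold and the proneural gene Neurod4 1.73-fold. All fell in both pairs, but pairs I and II differed in size for Sag (log2 −0.23 and −1.57), Junb (−0.46 and −1.14) and Neurod4 (−1.02 and −0.52). For Fabp7 they were −1.57 and −1.35. The fit shares its spread across genes, so the p-values hardly reflect such gaps within a gene. The plexin gene Plxna2 fell 4.32-fold (97.9 ± 19.0 to 22.6 ± 1.18 CPM), the protease gene St14 4.53-fold and Stac3 4.20-fold. Raxos1 rose 8.16-fold, Sowahc 6.79-fold and Mfsd10 4.63-fold. Sowahc and Mfsd10 were at 0 in control replicate II and Stac3 in Jarid2_cKO replicate II, so these 3 folds rest on few UMIs, as does that of Raxos1, at 5.94 and 1.92 CPM in control. The count with the block was 30 with equal numbers of cells (10 higher, 20 lower), and no low-count filter without the block gave 6. Retinal ganglion cell genes rose as a list (median 0.33 over 7) and Mueller glia genes fell (−0.32 over 3), each with a camera adjusted p of 0.00187 that was 0.782 with an estimated correlation. With the block, late progenitor and rod genes (lower) and S phase genes (higher) passed too, but none did with an estimated correlation (adjusted p = 0.669 for each). Fry with the block passed only cone genes (lower, adjusted p = 0.00854), which camera did not (0.248). The class held 101 to 147 cells per sample.

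Amacrine cells, inhibitory interneurons, had 8 genes past the threshold with the block, 3 higher and 5 lower, and 0 of 13983 without it (60 at an unadjusted p under 0.05, 0 by DESeq2 and 8 by DESeq2 with the block). With the block the count was 2 with thinned UMIs (1 higher, 1 lower), 13 with DESeq2 size factors (4 and 9), 15 with equal numbers of cells (3 and 12), 20 with top-scoring Scrublet cells left out (3 and 17) and 147 with no low-count filter (63 and 84). Lman1 rose 1.89-fold (131 ± 2.36 to 248 ± 29.2 CPM, SD, n = 2, edgeR adjusted p = 0.00543) and Igfbpl1 1.61-fold. The keratin gene Krt73 fell 2.23-fold, the tight junction gene Cldn5 2.06-fold, the growth factor binding protein gene Igfbp5 2.03-fold and Id1, an inhibitor of bHLH factors on the late progenitor list, 1.68-fold. Cldn5 was at 59.0 and 249 CPM in control and 30.1 and 115 CPM in Jarid2_cKO. Krt73, Cldn5 and Igfbp5 were all among the top genes of the same own cluster, with 96.5% of its cells amacrine in the authors' annotation. The share of that cluster within the class was not compared between genotypes. Late progenitor genes fell as a list (median −0.21, camera adjusted p = 2.40e-04, and 0.571 with an estimated correlation), with 12 of 18 lower in both pairs and 7 lower adjusted over the list alone with the block. Neurogenic (−0.19), S phase (−0.22), Notch pathway (−0.13), vascular (−0.59) and Mueller glia genes (−0.06) fell and early progenitor genes rose (0.02), with adjusted p from 0.0150 to 0.0469, and at least 0.571 with an estimated correlation. Of the 13 early progenitor genes tested, 4 were higher and 2 lower in both pairs. The vascular list rested on 5 genes, with Cldn5 and Pdgfrb lower adjusted over the list alone with the block. Cldn5 was also a top gene of the amacrine cluster given above. Cone genes were called lower (adjusted p = 0.0372, and 0.571 with an estimated correlation) with a mean of −0.24 but a median of 0.02. Early progenitor, Mueller glia, S phase and vascular genes did not pass with top-scoring Scrublet cells left out (adjusted p from 0.0611 to 0.161). The block added pan progenitor, amacrine, rod, G2M phase and dissociation stress genes, all lower, and none of these 5 passed with an estimated correlation (adjusted p from 0.619 to 0.733). After thinning of UMIs, Krt73, Igfbp5, Igfbpl1 and Id1 no longer passed with the block (adjusted p from 0.0584 to 0.208).

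Retinal ganglion cells, the output neurons, had 0 of 12620 genes past the threshold with or without the block. At an unadjusted p under 0.05 edgeR gave 62 genes without and 369 with the block, and DESeq2 called 0 in both. With the block, equal numbers of cells gave 15 genes (8 higher, 7 lower) and no low-count filter 56 (35 and 21), or 7 without the block. Late progenitor genes (median −0.20 over 18), amacrine (−0.30), cone (−0.33), rod (−0.50), G2M phase (−0.13) and dissociation stress genes (−0.16) fell and horizontal cell genes rose (0.11), with camera adjusted p from 0.00253 to 0.0320. With an estimated correlation none passed (smallest adjusted p = 0.552). With top-scoring Scrublet cells left out horizontal cell genes turned to a mean of −0.0535, and amacrine, rod and G2M phase genes did not pass (adjusted p from 0.0981 to 0.590). Pan progenitor genes passed with the block (lower), but not with an estimated correlation (adjusted p = 0.665). Adjusted over the list alone with the block, Meis2 rose and Ptf1a, Tfap2c and Prdm13 fell among amacrine genes, and Lhx1 rose among horizontal cell genes.

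Summed over all singlets, 16 genes passed with the block, 11 higher and 5 lower, and 0 of 17473 without it (123 at an unadjusted p under 0.05, 8 by DESeq2 and 35 by DESeq2 with the block). With the block the count was 4 with thinned UMIs (3 higher, 1 lower), 8 with top-scoring Scrublet cells left out (5 and 3), 54 with no low-count filter (27 and 27) and 71 with equal numbers of cells (33 and 38). These sums also move with the cell composition given above. Lman1 rose 2.52-fold, Samsn1 2.26-fold and Sfrp2 1.68-fold, and Krt73 fell 1.98-fold and Cldn5 1.84-fold. After thinning of UMIs, Sfrp2, Krt73 and Cldn5 no longer passed with the block (adjusted p from 0.0508 to 0.0940), and Krt73 also not with top-scoring Scrublet cells left out (0.0776). Early progenitor (median 0.18) and horizontal cell genes (0.33) rose. Late progenitor (−0.12), retinal ganglion cell (−0.15), G2M phase (−0.07), non-retinal developmental (−0.26) and microglia genes (−0.41) fell, with camera adjusted p from 2.37e-04 to 0.0168. None of them passed with an estimated correlation (smallest adjusted p = 0.452). With the block, pan progenitor, neurogenic, Mueller glia and vascular genes passed too (all lower), but not with an estimated correlation (adjusted p = 0.606 for each).

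Whether the genotype effect differed between progenitors and another class was tested directly, and no gene passed against neurogenic cells, photoreceptor precursors, cones, rods, amacrine cells or retinal ganglion cells, with or without the block. Beside these counts of 0, limma gave 139 (photoreceptor precursors) to 367 (neurogenic cells) genes at an unadjusted p under 0.05 without the block and 519 (rods) to 725 (amacrine cells) with it, and no other tool was run. The classes of 1 animal are not independent, so genes called in one class and not in another are not shown to differ between them.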

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

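The tests of the Cre allele, of free RNA, of UMI depth and of embryo age were chosen after the result was seen, and that of less advanced cones before.

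The share of barcodes outside the authors' annotation was above both control samples in both Jarid2_cKO samples, at 25.6% in replicate I and 22.6% in replicate II against 13.4 and 21.8% in control replicates I and II. These barcodes enter no comparison. Their median was 1433 to 1763 UMIs per sample.

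In Jarid2_cKO progenitors 3 genes near Rax, Raxos1, Lman1 and Tubb6 (at 0, 41.0 and 1451 kb), rose with the block. Within 2 Mb of Rax 3 of 36 tested genes were called, against 39 of 15556 elsewhere (one-sided Fisher's exact p = 0.000122), but the window was drawn after these genes had been seen, so the count restates the pattern and decides nothing. For the 3 genes the Cre allele at Rax, or the haplotype around it, cannot be told apart from loss of Jarid2, since 0 control libraries carry the Cre allele. The Cre allele and Cre activity are likewise confounded with loss of Jarid2 in every other genotype difference given here. These include the cone share, Foxp1, the cone genes and the progenitor lists.

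The 30 genes lower in Jarid2_cKO cones were set against 3 explanations. Free RNA from other cells was taken to give drops no larger than the control amacrine level. The lower quartile of the drop over that level was 3.962, with 25 of 30 genes above the amacrine level. Control cones held fewer UMIs than amacrine cells (medians of 4573.5 against 9510 in replicate I and 3992 against 7467 in replicate II), so free RNA could weigh more in their CPM. The 30 genes were also chosen by their drop, which limits this test. Thinning kept a median of 0.9955 of the log2 fold change of the 30 lower genes. It cuts all genes of a library at the same rate and leaves expected CPM ratios unchanged, so it cannot decide on UMI depth. A cone class less advanced from precursor to cone stays open: the precursor-high minus the cone-high median was 0.1387 as a mean over the 2 pairs, which differed (medians of 0.11 and −0.15 in pair I, −0.02 and −0.04 in pair II). The calls rest on edgeR with the block, so the pattern remains a hypothesis.

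Early progenitor genes were higher and late progenitor genes lower in Jarid2_cKO progenitors by camera at its preset correlation only, with adjusted p of 0.687 and 0.777 at an estimated correlation and 0.671 for both with fry. Thinning kept 0.8694 of the gap between the list medians, but it cuts all genes of a library alike, so it cannot decide on UMI depth. Jarid2_cKO embryos younger than their littermates would hold a larger progenitor share, and its blocked log2 ratio was −0.1367 with an interval that includes 0, so age cannot be told apart from an effect of Jarid2 loss. With 1 embryo of each genotype per litter the design does not part them.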

How the results depend on the processing

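The tests with Scrublet cells left out, those joining the block with another choice, and own clusters grouped by the main class of the authors, were chosen after the result was seen. Counts of genes past the threshold are in the order all cells, progenitors, neurogenic cells, photoreceptor precursors, cones, rods, amacrine cells and retinal ganglion cells. Without the block, edgeR gave 0 in each (unadjusted counts stand in the report), also with DESeq2 size factors, thinned UMIs, equal numbers of cells or Scrublet cells left out. No low-count filter gave 0, 0, 18, 10, 11, 6, 0, 7, and DESeq2 8, 9, 2, 0, 1, 0, 0, 0. With the block the counts were 16, 42, 12, 4, 44, 52, 8, 0. Joined to the block, DESeq2 size factors gave 16, 56, 14, 0, 42, 52, 13, 0, no low-count filter 54, 58, 113, 140, 53, 48, 147, 56, thinned UMIs 4, 61, 12, 53, 52, 42, 2, 0, equal numbers of cells 71, 45, 34, 85, 42, 30, 15, 15, Scrublet cells left out 8, 47, 62, 113, 12, 52, 20, 0, and DESeq2 35, 30, 7, 8, 1, 1, 8, 0. The cause of these differences was not tested. The log2 cone share of 0.85 passed with the block (0.84), also with TMM factors over classes (0.95), Scrublet cells left out (0.85), glia left out (0.84) or own clusters grouped by main class (0.83). Grouped so without the block it was 0.84 and did not pass. Own clusters named by markers give no cone share. The progenitor lists lost their calls with an estimated correlation and with fry, at means of 0.23 (early) and −0.13 (late), and of 0.23 and −0.12 with the block. Each of the 42 list calls of the report made without the block was lost in the same way under both methods, and so were the list calls gained with the block when the block was kept. Scrublet cells left out turned horizontal cell genes in ganglion cells to −0.0535 and ended 9 further list calls (2 in precursors, 4 in amacrine and 3 in ganglion cells), and the block turned Jarid2 in cones to −0.0218 (−0.0248 with DESeq2 size factors, −0.018 with DESeq2). The block changed no other call than those given beside the results.

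Leaving out each sample in turn, without the block, leaves 1 sample in a group, taken to vary like the other group. It also mixes genotype with batch, so the ranges below show the batch as well. Over these fits the list results lost their call 75 times, were unchanged 69 times, changed sign 26 times and gained a call 2 times. Counts ranged as follows: all cells 0 to 1, progenitors 0 to 1, neurogenic cells 0 to 2, precursors 0 to 2, cones 0 to 16, rods 0 to 14, amacrine cells 0 to 2, ganglion cells 0 to 9. The most calls came without Jarid2_cKO replicate I in cones and without control replicate II in rods. Log2 shares and list means ranged as follows: share of amacrine cells 0.0158 to 0.29, share of cones 0.51 to 1.19, share of glia −0.35 to 0.73, share of horizontal cells 0.40 to 1.18, share of neurogenic cells −0.0334 to 0.27, share of precursors 0.0969 to 0.23, share of ganglion cells −0.55 to −0.0125, share of progenitors −0.25 to −0.0327, share of rods −0.88 to 0.66, retinal ganglion cell genes in all cells −0.24 to 0.028, non-retinal developmental regulators in all cells −1.37 to 0.39, microglia genes in all cells −1.48 to 0.16, early progenitor genes in progenitors 0.16 to 0.29, late progenitor genes in progenitors −0.18 to −0.058, neurogenic genes in progenitors −0.66 to 0.17, retinal ganglion cell genes in progenitors −0.96 to 1.49, cone genes in progenitors −0.78 to 0.0504, G2M phase genes in progenitors −0.13 to 0.0121, late progenitor genes in neurogenic cells −0.49 to 0.019, late progenitor genes in precursors −0.49 to 0.19, retinal ganglion cell genes in precursors −0.37 to 0.96, rod genes in precursors −0.59 to 0.25, vascular genes in precursors −1.14 to 0.40, late progenitor genes in amacrine cells −0.56 to 0.17, neurogenic genes in amacrine cells −0.39 to 0.0573, cone genes in amacrine cells −0.64 to 0.0347, Mueller glia genes in amacrine cells −0.44 to 0.11, S phase genes in amacrine cells −0.62 to 0.46, cone genes in ganglion cells −0.68 to 0.62, G2M phase genes in ganglion cells −0.93 to 0.45. Single genes ranged as follows: Cldn5 in all cells −2.0 to 0.28, Jarid2 in all cells −0.16 to 0.23, Rax in all cells −0.56 to 0.46, Jarid2 in progenitors −0.24 to 0.0679, Rax in progenitors −0.41 to 0.56, Rax in neurogenic cells −1.001 to 0.12, Jarid2 in precursors −0.45 to 0.35, Rax in precursors −0.91 to 0.57, Jarid2 in cones −0.50 to 0.46, Rax in cones −1.06 to 0.62, Jarid2 in rods −0.47 to 0.045, Rax in rods −1.24 to 0.39, Cldn5 in amacrine cells −2.35 to 0.29, Jarid2 in amacrine cells −0.15 to 0.27, Rax in amacrine cells −0.54 to 0.14, Jarid2 in ganglion cells −0.19 to 0.27, Junb in rods −1.85 to 0.36.

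On simulated counts with the block, 1.5-fold changes were recovered for 40 of 66 genes in progenitors, 13 of 65 in cones and 9 of 62 in rods. No simulation varied depth alone, and the classes also differ in cell number and dispersion.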
